A study of Mus musculus with 7 samples.

How the data were processed

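Total RNA of mouse aorta was extracted with Trizol and made into libraries from 2 µg each with a SMARTER mRNA-Seq kit, per the labels' protocols. Genotype was the only factor in the labels, which give 4 WT and 3 KO libraries, each with a replicate number. The authors deposited 1 table of estimated counts per gene for the 7 libraries, with Ensembl mouse gene identifiers. GRCm38 and mm10 are named in the submitters' processing notes. The aligner, the counting tool, the annotation release, the read layout and the strand setting are not given in the sources used here. The deposited estimated counts are whole numbers without scaling between libraries, so rounding left them as they were. Low values pile up at multiples of 4. Between 8 and 40, such values were 1.25 to 1.38 times as frequent as their neighbours. How many reads a count of 1 stands for was not determined, so the totals of 68151472 to 76926790 are given as deposited counts, not as reads.

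Of 47729 identifiers, 47224 matched a gene symbol and 505 did not. The latter held between 0.049% and 0.0711% of the counts of a library and stayed in the tests under their identifier. Symbols carried by more than 1 identifier (120 identifiers) were left out of the gene lists and of the named genes. Positions come from GENCODE M21 on GRCm38 and are 1-based. Without the strand setting, reads of overlapping or antisense genes cannot be told apart, and reads of near-identical gene copies may be split between them.

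The comparison of KO with WT used R 4.3.3 and edgeR 4.0.16 on the counts as deposited. Genes were filtered with filterByExpr on the group, *Mmp19* and *Acan* being kept regardless, which left 19188 genes. Libraries were scaled by TMM, and genes were tested with glmQLFit and glmQLFTest without covariates. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes are those that match the quasi-likelihood F statistic. CPM, the counts scaled to a common library size with the TMM factors, are given as mean ± SD over libraries. Deviations of a gene list are medians over its genes of log2 CPM (prior count 2) minus the mean of the WT libraries. Single genes and list means were also compared by an exact 2-sided permutation test over the 35 splits of the 7 libraries into 4 and 3, which was chosen after the first results had been seen.

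A set of 41 gene lists with 963 genes was written before the data were examined, together with the tests, the alternatives and the rule for naming genes. The lists cover the vessel wall, the pathways named in the series title, other cell types and RNA quality, and some genes stand on more than 1 list. Lists with 5 or more tested genes were tested 2-sided with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry, in its test for a common direction and its test for changes in either direction. P-values of lists were adjusted over the 41 lists. For the genes of a list, a second adjustment of edgeR's p-values over the list alone is given. The rule named *Mmp19* and *Acan*, then, among genes past the threshold with a mean of 2 CPM or more and groups that do not overlap, the 12 largest and 4 most abundant in each direction. It also named the 4 members of each list with the smallest p. As 3 genes passed the threshold, these were all taken. *Acta2*, *Myh11*, *Lyz2*, *Myh6*, *Col1a1*, *Sox9*, *Axin2*, *Ddx3y*, *Pln*, *Myh10*, *Vim*, *Nes* and *Mmp17* fall outside the rule and were named after their values had been seen.

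The procedure was tested on simulated counts with the means and library sizes of these data, in which 200 of 19188 genes were changed. With the real spread, 20% of the genes changed 2-fold and 95% of those changed 8-fold were recovered for KO against WT, with 10 unchanged genes called. With the dispersion, a squared coefficient of variation, reduced 4-fold the shares were 68% and 100%, with 7 unchanged genes called. Libraries were compared pairwise for duplicates by a chi-square of their counts divided by 4.

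The alternatives planned were DESeq2's size factors and upper-quartile scaling in edgeR, no filter, a filter of 50 counts in at least 3 libraries, removal of mitochondrially encoded genes, DESeq2 1.42.0, limma-voom with sample quality weights, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were division of the counts by 4, a robust and a legacy quasi-likelihood fit, and removal of marker genes of adjoining tissues. All 7 columns of the table were used.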

Results

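RNA was sequenced from the aorta of wild-type mice (WT, 4 libraries) and of mice labelled as *Mmp19* knockouts (KO, 3 libraries). *Mmp19* encodes a secreted matrix metalloproteinase, and the comparison asks which transcripts of the vessel wall differ when it is deleted. The series title places the protease in smooth muscle cells, in a protective axis with aggrecan and Wnt/β-catenin signalling, in thoracic aortic aneurysm and dissection. Estimated counts per library summed to between 68151472 and 76926790, and between 22785 and 23961 genes had a count above 0. The labels do not state that each library came from a separate mouse, so p-values of single genes and of permutations measure the spread between these 7 libraries. Those of camera at the preset correlation of 0.01 set the genes of a list against the other genes. They treat these genes as nearly independent and do not measure the spread between libraries. For the interferon list the estimated correlation was 0.517. No library was a duplicate of another, since each pair differed by far more than sampling noise (mean chi-square per gene of 26.2 or more).

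The targeted gene was measured first. *Mmp19* (chromosome 10, 128790910 to 128800824, GRCm38) was still counted in the KO libraries, at 17.8 ± 6.96 CPM (counts scaled to a common library size; SD, n = 3) against 26.2 ± 5.96 CPM in WT (SD, n = 4). The single WT libraries read 24.8, 24.8, 20.7 and 34.7 CPM. KO replicates 1, 2 and 3 read 25.5, 12 and 15.9 CPM, so that KO replicate 1 lay inside the WT range. The log2 fold change of -0.56 (SE 0.29) did not pass the test (edgeR quasi-likelihood, adjusted p = 0.368), and an exact permutation of the 7 labels gave p = 0.2, 2-sided. Counts per gene do not show which exons the reads came from, so this value neither bears out nor contradicts the labels, and KO below means a library labelled knockout. The 41 tested genes that flank *Mmp19* on its chromosome had a median log2 fold change of 0.05 (camera, adjusted p = 0.399). *Ddx3y*, on the Y chromosome, was at 92.4 to 135 CPM and *Xist*, which marks the inactive X chromosome, at 0.842 CPM or less in every library, so that the groups did not differ in sex. The 5 sex-linked genes had a median log2 fold change of 0.00 (camera, adjusted p = 0.614).

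A cartilage collagen, a short-chain collagen and a bone-related receptor separated the groups, and all were higher in KO. *Col10a1*, the collagen of hypertrophic cartilage (chromosome 10, 34389981 to 34397085), averaged 75.0 ± 40.8 CPM in KO (SD, n = 3) and 0.264 ± 0.157 CPM in WT (SD, n = 4), a log2 fold change of 8.15 (SE 0.62, edgeR adjusted p = 0.0365). Its KO libraries read 114, 32.7 and 78.1 CPM, while no WT library exceeded 0.486 CPM. *Col8a1*, a short-chain collagen made by activated smooth muscle (chromosome 16, 57624258 to 57754737), rose from 24.1 ± 7.29 to 340 ± 113 CPM (log2 fold change 3.82, SE 0.33, edgeR adjusted p = 0.0386). *Tnfrsf11b*, which encodes the decoy receptor osteoprotegerin (chromosome 15, 54250619 to 54278484), rose from 10.01 ± 2.16 to 57.8 ± 14.7 CPM (log2 fold change 2.53, SE 0.23, edgeR adjusted p = 0.0386). For each of these genes every KO library lay above every WT library, and the exact permutation p was 0.0286, the smallest that 7 libraries can give. The genes were picked from the same libraries, by a rule that required groups without overlap, so neither value is added support.

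These 3 genes were all that passed edgeR's quasi-likelihood test among the 19188 tested, and 0 genes were lower. At an unadjusted p under 0.05 there were 3299 genes, of which 1904 were higher and 1395 lower in KO. DESeq2 called 1606 genes, 1020 higher and 586 lower, with the 3 edgeR genes among them, and limma-voom called 7, all higher. The quality weights in limma-voom were lowest for KO replicate 1 (0.256) and highest for WT replicate 4 (2.61). Its values below are therefore not a check separate from leaving out KO replicate 1. KO and WT did not overlap for 16.7% of the genes, where chance gives 5.71%. The count of 3 fell to 0 without any 1 of the 4 WT libraries, without KO replicate 1 or without KO replicate 3. It was 1029 without KO replicate 2, the KO library closest to WT. On the first principal component (38.7% of the variance) KO replicates 1, 2 and 3 scored 130.9, 8.92 and 35.6, and the WT libraries between -78.9 and -28.9.

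**Figure D1:**
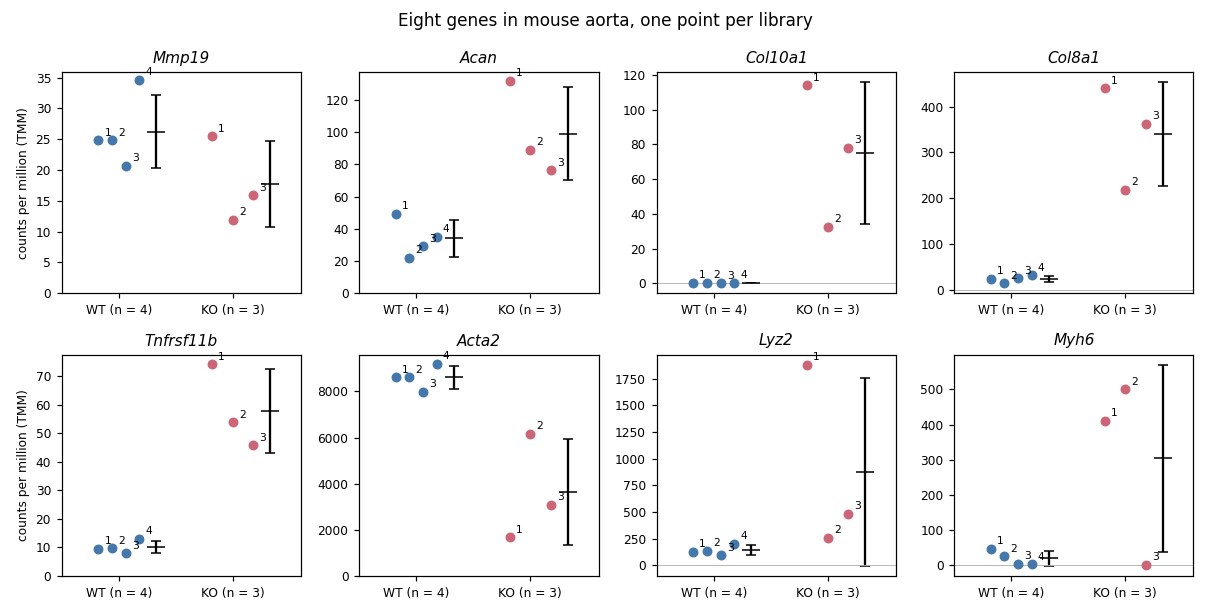
Each panel plots the CPM (TMM-scaled counts) of 1 gene, one point per library with its replicate number, for WT (blue, n = 4) and KO (red, n = 3); the black mark and bars give the group mean and SD. Col10a1, Col8a1 and Tnfrsf11b lie higher in all 3 KO libraries, Mmp19 overlaps between the groups, and Myh6 is at 411 and 500 CPM in KO replicates 1 and 2 but at 0.738 CPM in KO replicate 3.

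Aggrecan, the large cartilage proteoglycan that the title names, was higher in every KO library. *Acan* (chromosome 7, 79053483 to 79115099) averaged 99.0 ± 29.0 CPM in KO (SD, n = 3) and 34.0 ± 11.6 CPM in WT (SD, n = 4). Its log2 fold change of 1.54 (SE 0.30) did not pass the correction over all genes in edgeR (adjusted p = 0.165), while DESeq2 gave an adjusted p of 0.000233 and edgeR without KO replicate 2 gave 0.0478. The exact permutation p was 0.0286, 2-sided. Proteoglycans and their link proteins did not pass as a group, with a median log2 fold change of -0.21 over 37 genes, a mean of 0.18 and a camera adjusted p of 0.5. Adjusted over the list alone, 7 were higher and 1 was lower. Over all genes tested, edgeR called 0 of them and DESeq2 9 higher and 1 lower. Among them *Lum*, the collagen-binding proteoglycan lumican, averaged 452 ± 32.2 CPM in KO and 187 ± 37.3 CPM in WT, and *Cspg4*, a pericyte and smooth muscle proteoglycan, 279 ± 93.6 and 508 ± 39.8 CPM (SD, n = 3 and 4).

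The Wnt/β-catenin target genes showed no common direction. Their median log2 fold change was -0.08 over 28 genes, the mean was 0.11, and camera gave an adjusted p of 0.773 with its direction upward. When adjusted over the list alone, *Ccn4* was higher (58.7 ± 40.5 against 9.86 ± 2.26 CPM), and *Nkd1* (18.9 ± 7.20 against 41.6 ± 4.23 CPM) and *Dact1* (23.0 ± 2.71 against 33.6 ± 3.12 CPM), both inhibitors of the pathway, were lower. *Axin2*, a feedback target often read as a measure of the pathway, was at 9.75 ± 2.71 CPM in KO and 9.78 ± 1.47 CPM in WT (SD, n = 3 and 4). The 33 Wnt ligands and receptors had a median log2 fold change of -0.16 (camera, adjusted p = 0.0847), which was -0.078 without WT replicate 1. This list was called without WT replicate 2 (median -0.23, camera adjusted p = 0.0202) and without KO replicate 2 (median -0.236, camera adjusted p = 0.0347). The 17 genes listed as Wnt antagonists had a median of 0.23 (camera adjusted p = 0.0847). This median was 0.0499 without KO replicate 1, and the list was called without WT replicate 3 (median 0.30, camera adjusted p = 0.0394). *Cthrc1*, a secreted glycoprotein of injured arteries that stands on this list but is not a plain inhibitor, averaged 78.9 ± 50.7 CPM in KO and 6.08 ± 1.74 CPM in WT. *Wif1*, a secreted inhibitor that binds Wnt proteins, averaged 18.6 ± 9.90 and 49.1 ± 15.5 CPM. Adjusted over the list alone, 4 genes of the antagonist list were higher and 1 was lower. Over all genes tested, edgeR called 0 of the Wnt genes, while DESeq2 called 1 higher and 5 lower among ligands and receptors, 3 higher and 3 lower among targets, and 4 higher and 2 lower on the antagonist list. The 26 genes of the TGF-β pathway had a median of 0.06 (camera, adjusted p = 0.601), and *Thbs1*, a matricellular activator of TGF-β, averaged 1134 ± 848 CPM in KO and 247 ± 103 CPM in WT.

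The contractile apparatus of smooth muscle was lower in KO. Of 25 contractile genes 23 had a negative log2 fold change, with a median of -1.09 (camera with a preset correlation, adjusted p = 3e-14; adjusted p = 0.437 with an estimated correlation). Smooth muscle actin, *Acta2*, averaged 3640 ± 2297 CPM in KO and 8605 ± 495 CPM in WT, and smooth muscle myosin, *Myh11*, 1798 ± 1232 and 4916 ± 507 CPM (SD, n = 3 and 4). *Hspb6*, *Tpm2* and *Actg2* had log2 fold changes of -1.13, -1.22 and -1.17. When adjusted over the list alone, 16 genes were lower and 2 were higher. Over all genes tested, edgeR called 0 contractile genes and DESeq2 13 lower and 2 higher. The higher genes in the list-alone adjustment were *Pln* and *Casq2*, calcium-handling genes that heart muscle also expresses. The size differed between libraries, with median log2 deviations from the WT mean of -1.99 in KO replicate 1, -0.38 in KO replicate 2 and -1.27 in KO replicate 3. By the mean of the contractile list, 2 of the 3 KO libraries lay below all WT libraries, and the exact permutation p was 0.0571. Markers of pericytes and small-vessel mural cells lay lower as well, with a median of -0.23 over 16 genes (camera, adjusted p = 0.0348; adjusted p = 0.437 with an estimated correlation). The pericyte call was lost without WT replicate 4 (adjusted p = 0.103), without KO replicate 3 (median -0.12, adjusted p = 0.0963) and with DESeq2's statistics (adjusted p = 0.0593), and the median was -0.37 without KO replicate 2. Basement membrane genes had a median of -0.48 over 20 genes (camera, adjusted p = 0.00312; adjusted p = 0.671 with an estimated correlation), and of -0.302 without WT replicate 1.

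Genes listed for modulated smooth muscle, the state that cells take up when they leave the contractile one, lay higher in KO. RNA of whole aorta does not show which cells made these transcripts. Their median log2 fold change was 0.73 over 23 genes (camera, adjusted p = 2.18e-09; adjusted p = 0.437 with an estimated correlation), and edgeR called 2 of them over all genes tested, *Col8a1* and *Tnfrsf11b*, where DESeq2 called 10 higher and 3 lower. Adjusted over the list alone, 11 were higher and 3, *Myh10*, *Vim* and *Nes*, were lower. *Spp1*, osteopontin, averaged 405 ± 544 CPM in KO and 3.22 ± 1.44 CPM in WT (SD, n = 3 and 4), with 1029, 41.0 and 143 CPM in KO replicates 1, 2 and 3. Its log2 fold change of 6.97 was 4.83 without KO replicate 1. *Spp1* ranked the KO libraries as the macrophage list did, whose deviations were 3.02, 0.80 and 1.80, so macrophages as its source cannot be told apart from smooth muscle. *Vcam1*, an adhesion molecule for leukocytes that also stands on the inflammatory list, averaged 130 ± 24.3 CPM in KO and 56.4 ± 10.1 CPM in WT. The cartilage programme had a median of 0.65 over 22 genes (camera, adjusted p = 0.000279; adjusted p = 0.437 with an estimated correlation), which was 0.197 without KO replicate 1 and 0.36 without WT replicate 1. Its deviations were 1.75, 0.65 and 0.35 in KO replicates 1, 2 and 3 and -0.24 to 0.33 in WT, so that KO replicate 3 lay close to the highest WT library. Over all genes tested, edgeR called *Col10a1* alone among them and DESeq2 6 higher and 1 lower, and 5 cartilage genes were higher when adjusted over the list alone. Besides *Col10a1* and *Acan* these were *Col2a1*, the main cartilage collagen (14.1 ± 11.6 against 0.831 ± 0.533 CPM), *Runx2*, a bone and hypertrophic cartilage transcription factor (9.98 ± 7.31 against 1.74 ± 0.292 CPM), and *Col11a1* (56.9 ± 53.8 against 3.49 ± 3.17 CPM). *Sox9*, the early cartilage transcription factor, averaged 8.40 ± 5.47 CPM in KO and 3.91 ± 0.924 CPM in WT and passed neither of edgeR's adjustments.

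The fibrillar and associated collagens had a median log2 fold change of 0.38 over 27 genes (camera, adjusted p = 0.00392; adjusted p = 0.697 with an estimated correlation). The collagen call was lost without WT replicate 2 (adjusted p = 0.108), without KO replicate 1 (median 0.0678, adjusted p = 0.0656) and with limma-voom (median 0.11, adjusted p = 0.394). This list also holds genes that are not collagens, among them *P4ha3* and *Pcolce2*. Over all genes tested, edgeR called *Col8a1*, and DESeq2 called 5 genes of the list higher and 2 lower. Adjusted over the list alone, 5 of its genes were higher and 1, *Pcolce2*, lower. *Col1a1*, a chain of type I collagen, averaged 6521 ± 2774 CPM in KO and 4872 ± 1621 CPM in WT (edgeR, adjusted p = 0.605). Elastic fibre genes had a median of 0.26 over 23 genes (camera, adjusted p = 0.16), and *Fbn2*, a fibrillin of developing vessels, was higher when adjusted over the list alone (19.6 ± 15.8 against 0.954 ± 0.631 CPM). The elastic fibre median was 0.0465 without KO replicate 1. That list was called without WT replicate 1 (median 0.37, camera adjusted p = 0.0169) and without KO replicate 3 (median 0.31, camera adjusted p = 0.025). The metalloproteinases and their TIMP inhibitors had a median of 0.01 and a mean of 0.70 over 22 genes (camera, adjusted p = 0.113). When adjusted over the list alone, 6 were higher and 1, *Mmp17*, lower. *Timp1* averaged 105 ± 100 CPM in KO and 11.6 ± 2.30 CPM in WT, and *Mmp12*, the macrophage elastase, 9.98 ± 7.31 and 0.791 ± 0.416 CPM (SD, n = 3 and 4). The 23 genes of the ADAMTS list, which also holds the ADAMTS-like *Adamtsl5*, had a median of -0.23 (camera, adjusted p = 0.773). *Adamts4*, an aggrecan-cleaving protease, was higher when adjusted over the list alone (23.7 ± 17.4 against 3.01 ± 0.311 CPM). Without 1 library the ADAMTS median ran from -0.29 to -0.019.

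Macrophage transcripts were more abundant in KO. The median log2 fold change of 26 macrophage and monocyte genes was 2.17, and 25 of them were positive (camera, adjusted p = 2.31e-20; adjusted p = 0.437 with an estimated correlation). Adjusted over the list alone, 20 were higher, while over all genes tested edgeR called 0 and DESeq2 19. *Lyz2*, lysozyme, averaged 874 ± 877 CPM in KO and 142 ± 45.9 CPM in WT, *C1qb*, a complement subunit made by resident macrophages, 146 ± 88.7 and 36.1 ± 8.47 CPM, and *Cx3cr1*, the fractalkine receptor, 26.4 ± 20.6 and 2.84 ± 0.914 CPM (SD, n = 3 and 4). As for the contractile genes, KO replicate 1 deviated most, with medians of 3.02, 0.80 and 1.80 in KO replicates 1, 2 and 3, and the median log2 fold change was 1.38 without KO replicate 1 and 1.58 with limma-voom. Neutrophil and mast cell genes had a median of 0.85 over 19 genes (camera, adjusted p = 0.000503; adjusted p = 0.439 with an estimated correlation), and 7 were higher when adjusted over the list alone. The median of these genes was 0.32 with the stricter filter or with counts divided by 4. *Csf3r*, the receptor for granulocyte colony-stimulating factor, read 173, 3.87 and 23.8 CPM in the KO libraries and 2.38 CPM or less in WT. B and plasma cell genes had a median of 1.07 over 22 genes (camera, adjusted p = 0.00127; adjusted p = 0.595 with an estimated correlation), and 0 passed when adjusted over the list alone. They deviated by 1.58, -0.0406 and 1.08 in KO replicates 1, 2 and 3 and by -0.96 to 0.697 in WT, and the median was 0.62 without KO replicate 1.

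All 31 inflammatory cytokines, chemokines and adhesion molecules had a positive log2 fold change, with a median of 2.42 (camera, adjusted p = 3.24e-20; adjusted p = 0.437 with an estimated correlation). When adjusted over the list alone, 21 were higher, among them *Il1b*, interleukin 1β (15.5 ± 13.5 against 0.257 ± 0.135 CPM), and *Cxcl16*, a chemokine (34.1 ± 15.2 against 11.1 ± 0.698 CPM). The inflammatory genes deviated by 2.45, 0.61 and 2.45 in KO replicates 1, 2 and 3, and their median log2 fold change was 1.57 without KO replicate 1, 1.71 without KO replicate 3, 1.76 with the stricter filter and 1.84 with limma-voom. All 32 interferon-response genes were positive as well, with a median of 1.07 (camera, adjusted p = 1.49e-22; adjusted p = 0.437 with an estimated correlation), and 23 were higher when adjusted over the list alone. *Bst2*, which tethers virus particles, averaged 49.8 ± 5.31 CPM in KO and 23.0 ± 3.73 CPM in WT, *Rsad2*, viperin, 29.0 ± 6.48 and 12.8 ± 1.75 CPM, and *Irf7*, a transcription factor of the response, 35.3 ± 14.0 and 10.3 ± 2.71 CPM (SD, n = 3 and 4). The interferon genes deviated by medians of 0.94, 0.76 and 1.48 in KO replicates 1, 2 and 3, a narrower spread than that of the macrophage genes.

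Dividing-cell genes were higher in KO, and most so in KO replicate 1. All 30 cell cycle genes were positive, with a median log2 fold change of 1.74 (camera, adjusted p = 4.06e-13; adjusted p = 0.459 with an estimated correlation), and 24 were higher when adjusted over the list alone. Their deviations were 2.85, 0.44 and 0.87 in KO replicates 1, 2 and 3 and up to 0.34 in WT, and the median log2 fold change was 0.62 without KO replicate 1 and 1.04 with limma-voom. By the mean of the cell cycle list, 2 of the 3 KO libraries lay above all WT libraries, and the exact permutation p was 0.0571. *Birc5*, survivin, read 21, 4.11 and 7.16 CPM in the KO libraries and 1.76 to 4.04 CPM in WT. Chaperones of the unfolded protein response had a median of 0.53 over 24 genes (camera, adjusted p = 2.19e-08; adjusted p = 0.437 with an estimated correlation), which was 0.31 without KO replicate 1 and 0.28 with limma-voom. Adjusted over the list alone, 11 were higher, among them *Hspa5*, the chaperone BiP (964 ± 218 against 559 ± 81.7 CPM), and *Manf* (109 ± 26.4 against 54.4 ± 9.53 CPM). Targets of p53 and senescence genes had a median of 0.42 over 21 genes (camera, adjusted p = 0.0116; adjusted p = 0.437 with an estimated correlation), with *Ccng1* (185 ± 15.9 against 123 ± 8.24 CPM) and *Pmaip1* higher when adjusted over the list alone. The p53 median was 0.25 without KO replicate 1 and 0.27 with limma-voom. Ribosomal protein genes had a median of 0.15, and 33 of 34 were positive (camera, adjusted p = 0.00128; adjusted p = 0.671 with an estimated correlation).

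Energy metabolism genes stood lowest in KO replicate 1, with median log2 deviations from the WT mean of -1.49 for fatty acid oxidation and -1.18 for oxidative phosphorylation. Fatty acid oxidation genes had a median log2 fold change of -0.31 over 24 genes (camera, adjusted p = 0.0216; adjusted p = 0.819 with an estimated correlation). That call was lost without KO replicate 1 (median 0.0622, adjusted p = 0.553), without WT replicate 2 (median -0.0865, adjusted p = 0.163), with DESeq2's statistics (adjusted p = 0.11) and with limma-voom (median -0.022, adjusted p = 0.841), and the median was -0.47 without WT replicate 3 and -0.75 without KO replicate 3. Markers of brown adipocytes deviated by -1.87 in KO replicate 1, 0.64 in WT replicate 2 and -0.45 in WT replicate 3, where fatty acid oxidation genes deviated by -1.49, 0.48 and -0.52, and those of white and general adipocytes by -0.76, 0.53 and -0.26. Oxidative phosphorylation genes had a median of -0.15 over 32 genes (camera, adjusted p = 0.0984), mitochondrially encoded genes -0.25 over 13 (adjusted p = 0.0811) and brown adipocyte genes -0.17 over 22 (adjusted p = 0.0847). The oxidative phosphorylation list was called with medians of opposite sign. These were 0.16 without KO replicate 1 (camera adjusted p = 0.00496) and -0.50 without KO replicate 3 (camera adjusted p = 4.8e-06). Mitochondrial transcripts took 5.95% of the counts of KO replicate 1 and between 9.99% and 15.3% in the other libraries. White and general adipocyte genes had a median of 0.03 over 24 genes (camera, adjusted p = 0.898, direction downward). That list too was called with opposite signs, at 0.27 without KO replicate 1 (camera adjusted p = 0.00111) and -0.30 without KO replicate 3 (camera adjusted p = 0.0196). Without KO replicate 3 the brown adipocyte and mitochondrially encoded lists were also called (medians -0.84 and -0.49, camera adjusted p = 0.000237 and 0.000327).

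Endothelial genes showed no difference that passed the test, with a median log2 fold change of 0.00 over 24 genes (camera, adjusted p = 0.601). Fibroblast and adventitial genes had a median of -0.16 over 24 genes (adjusted p = 0.146), immediate early and heat shock genes -0.26 over 28 (adjusted p = 0.62), and mesothelial genes 0.27 over 18 (adjusted p = 0.0765). The immediate early list was called without WT replicate 2 (median -0.28, camera adjusted p = 0.00308), and the mesothelial list, among other settings, without KO replicate 1 (median 0.51, camera adjusted p = 0.000114). The fibroblast median was -0.0738 without WT replicate 1, and that list was called without KO replicate 2 (median -0.19, camera adjusted p = 0.0422). Lymphatic endothelial genes had a median of 0.41 over 12 genes (camera, adjusted p = 0.0234; adjusted p = 0.437 with an estimated correlation), a call lost without WT replicate 2 (adjusted p = 0.0836), without KO replicate 2 (adjusted p = 0.0766), with DESeq2's statistics (adjusted p = 0.0589) and with limma-voom (adjusted p = 0.0694). *Pdpn*, podoplanin, was the member that was higher when adjusted over the list alone (37.1 ± 23.5 against 9.53 ± 0.61 CPM). Erythroid genes had a median of 1.12 over 12 genes (adjusted p = 0.0558). Their list was called, among other settings, without KO replicate 1 (median 1.58, camera adjusted p = 5.05e-06), and its median was -0.0719 without KO replicate 3.

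Markers of tissues that adjoin the aorta differed between single libraries. Cardiac muscle genes had a median log2 fold change of 3.20 over 21 genes (camera, adjusted p = 4.84e-08; adjusted p = 0.437 with an estimated correlation), and their deviations from the WT mean were 3.68, 4.23 and -0.76 in KO replicates 1, 2 and 3. The cardiac median was 4.24 without KO replicate 3 and 0.78 with limma-voom. *Myh6*, the myosin of the heart, read 411, 500 and 0.738 CPM in these libraries and 47.0, 24.9, 3.63 and 2.35 CPM in WT. Skeletal muscle genes had a median of 2.73 over 22 genes (camera, adjusted p = 0.000381; adjusted p = 0.549 with an estimated correlation), with deviations of 0.24, 0.16 and 3.58. The skeletal call was lost without KO replicate 3 (median -0.0206, adjusted p = 0.293), and the median was 1.902 with the stricter filter. Of the skeletal genes, *Ckm*, muscle creatine kinase, which the heart also makes, was at 16.0, 17.5 and 30.1 CPM in the KO libraries and at 2.48 to 4.07 CPM in WT. Nerve and Schwann cell genes stood highest in WT replicate 3, with a deviation of 3.08 (median log2 fold change -1.28 over 25 genes, camera adjusted p = 0.0909). Their list was called with opposite signs, at 0.73 without WT replicate 3 (camera adjusted p = 0.0205) and -2.15 without KO replicate 3 (camera adjusted p = 0.0102). T and NK cell genes (median -0.21 over 24 genes, camera adjusted p = 0.0847, direction upward) and thymocyte genes (median -0.39 over 11 genes, adjusted p = 0.488, direction upward) stood highest in WT replicate 2, with deviations of 2.01 and 2.15. Without WT replicate 2 both lists were called, with medians of 1.08 and 1.13 (camera adjusted p = 3.5e-09 and 0.00364).

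**Figure D2:**
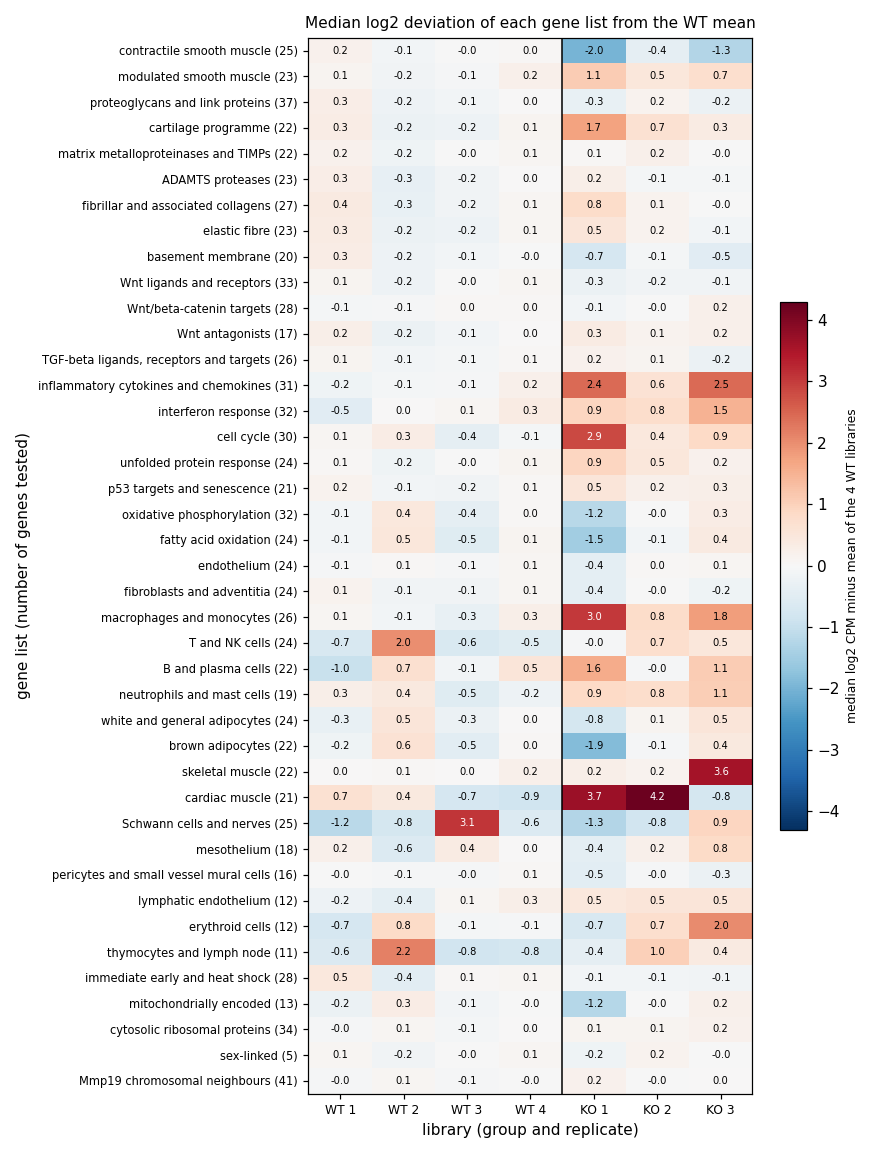
Heat map of the median log2 deviation of each gene list (vertical axis, number of tested genes in brackets) from the mean of the 4 WT libraries, one column per library (horizontal axis); red is higher and blue lower than the WT mean. Macrophage, inflammatory and interferon lists are above 0 in all 3 KO libraries, while the cardiac list is high in KO replicates 1 and 2, the skeletal list in KO replicate 3 and the nerve list in WT replicate 3.

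Of the 41 lists, 19 were called with camera's preset correlation of 0.01, 15 higher and 4 lower in KO. With a correlation estimated for each list 0 were called, and fry, which asks whether the genes of a list move on balance one way, called 0, while its test for changes in either direction called 23. In an exact permutation of the library labels on each list's mean log2 CPM, 8 lists reached the smallest possible p of 0.0286: modulated smooth muscle, the cartilage programme, metalloproteinases and TIMPs, inflammatory genes, interferon response, unfolded protein response, macrophages, and neutrophils and mast cells. Adjusted over the 41 lists this p became 0.146, so none passed.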

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

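The tests of explanations below were chosen after the results had been seen, except the counts over other splits for edgeR genes, for lists and for DESeq2 genes. Those for edgeR genes and lists were set after the counts for the real groups were known but before any other split was computed. That for DESeq2 genes was set before its own splits were computed but after those for edgeR genes and lists had been seen.

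Among 200 groups of 4 WT values examined (158 genes, 41 lists and the totals), 16 held 1 library far from the other 3, which is 8% where chance gives about 5%. WT replicate 2 accounted for 10 of them and WT replicate 3 for 5. WT replicate 2 stood high for *Dntt*, a thymocyte enzyme (30.7 CPM against 2.38 to 3.31), for *Fabp3* (131 CPM against 69.7 to 74.2), *mt-Co1* (59388 CPM against 41018 to 43608), *Rpl32* (141 CPM against 119 to 122) and *Draxin* (0.225 CPM against 0.186 to 0.190). It also stood high for the T and NK cell list (median log2 deviation 2.01) and the thymocyte list (2.15). The same library stood low for *Wnt9a* (14.5 CPM against 16.9 to 17.4), *Mmp13* (0.253 CPM against 0.462 to 0.473) and *Il1r2* (0 CPM against 0.163 to 0.235). WT replicate 3 stood high for the nerve-expressed *Uchl1* (216 CPM against 28.9 to 34.6), the Schwann cell gene *Prx* (31.5 CPM against 11 to 13), the nerve and Schwann cell list (median log2 deviation 3.08) and *Ccl4* (0.0574 CPM against 0), and low for *Ccnb1* (2.01 CPM against 3.43 to 3.82). WT replicate 1 stood low for *H2-Oa* (0 CPM against 0.190 to 0.287). With the other 3 libraries at 0, any count of *Ccl4* would have been flagged. The flags of *Ccl4*, *Draxin*, *Il1r2* and *H2-Oa* rest on values near 0, and the 16 include them.

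A first pattern joins lower contractile genes with higher macrophage genes in KO, most so in KO replicate 1 and least in KO replicate 2. A smaller share of smooth muscle would raise all other cell types alike, but the macrophage median exceeded the endothelial median by 2.17 on the log2 scale (95% interval from resampling genes 1.64 to 2.80), which argues against that share as the whole cause. Heart muscle in the sample is no better account. KO replicate 1 carried somewhat less cardiac signal than KO replicate 2 (median difference -0.38, interval -0.95 to -0.21). Yet the contractile genes of KO replicate 1 lay lower than those of KO replicate 2 (median difference -1.62, interval -2.09 to -1.23). A wall with more macrophages and fewer contractile transcripts stays open as a hypothesis, and so does a difference in disease stage or dissected region between mice, which was not tested. These intervals cover genes, not mice.

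A second pattern is the striated muscle signal in KO. Attached heart muscle in KO replicates 1 and 2 cannot be told apart from a rise of these genes in the vessel wall of those libraries, since 16 of the 21 cardiac genes lay at least 4-fold above the WT mean in both, an outcome that either would give. A cardiac rise of the same size in all 3 KO libraries is argued against, since the cardiac median of KO replicate 3 minus the lower of those of KO replicates 1 and 2 was -4.44 (interval -6.03 to -2.54), where the medians of the 4 WT libraries spanned 1.53. A smaller change shared by all 3 cannot be told apart from no change in KO replicate 3, as its median deviation of -0.76 had an interval of -1.28 to 0.87, with 4 of its 21 cardiac genes above all 4 WT libraries (exact binomial interval 5.45% to 41.9%) and 10 below them, against 16 and 1 in KO replicate 1 and 18 and 0 in KO replicate 2. These counts were added because the median was inconclusive and the difference of -4.44 after both, and all rest on 1 library and on genes that move together.

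The last pattern is that *Mmp19* counts remained in KO, at 67.8% of the WT mean. A transcript still made from the targeted allele would leave such counts if the deletion spares most of the counted exons, and counts per gene cannot be told apart by exon, so this stays open. With 1 WT exchanged for 1 KO library, DESeq2 called at most 485 genes over the 12 possible exchanges, where the labelled groups gave 1606. This count shows how far apart the groups lie, whatever the cause. It therefore cannot tell whether the genotype labels of a WT and a KO library were exchanged. A single wrong label without a partner was not tested; KO replicate 1, at 25.5 CPM of *Mmp19*, was the library farthest from WT on the first principal component (130.9, against -78.9 to -28.9 in WT).

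Other splits of the 7 libraries into 4 and 3 number 35 with the real one. The real split was the only 1 to give 3 edgeR genes (highest other 0), the only 1 to reach 1606 DESeq2 genes (highest other 485) and the only 1 to reach 3299 genes at an unadjusted p under 0.05 (highest other 2294). That is a share of 0.0286 for each, the smallest that 35 splits allow and not adjusted for the number of counts examined, so chance can be excluded for the edgeR and DESeq2 counts only at that share, and the count at an unadjusted p was chosen after seeing the data. For the lists it cannot, as 21 of the 35 splits called 19 or more and another split called 26. The preset correlation therefore calls lists under other groupings of these libraries, which differ in several tissues at once. No split into 4 and 3 divides the genotypes evenly, so these counts do not show how many lists would be called without any group difference. A split that called 26 set WT replicates 2, 3 and 4 against WT replicate 1 and all KO libraries.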

How the results depend on the processing

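Division of the counts by 4, the robust and legacy fits and the removal of marker genes of adjoining tissues were chosen after seeing the data. The count of 3 genes, all higher, stayed at 3 with DESeq2's size factors or upper-quartile scaling, without mitochondrial genes, with the robust or legacy fit and without markers of adjoining tissues. It was 7, all higher, with the stricter filter, limma-voom or counts divided by 4, and 0 without a filter, where 29455 genes share the correction. DESeq2 called 1606 (1020 higher, 586 lower), and its adjusted p was not given for 2601 genes. Without 1 library the count ran from 0 to 1029 (0 to 667 higher, 0 to 362 lower), and all 3 genes remained in the 1029 without KO replicate 2. The cause was not tested. In simulated data 20% of 2-fold changes were recovered with the real spread and 68% with the dispersion reduced 4-fold. The simulated genes were drawn independently, without shifts that many genes of a library share. The simulation therefore cannot show what limited the calls in the real data. The log2 fold change of *Acan* was 1.56 and past the threshold in DESeq2, and ran from 1.28 to 1.81 without 1 library, past it only without KO replicate 2. That of *Mmp19* stayed negative and short of the threshold in all 19 alternatives, from -0.92 to -0.28. Lists called numbered 0 with an estimated correlation and 0 with fry's test for a common direction, both of which allow for genes of a list moving together, and 17 to 24 otherwise.

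Whether the replicate numbers pair the libraries is not given in the labels and could not be settled from the counts. Same-numbered libraries correlated by 0.05, 0.07 and 0.34 in their deviations from the group means, and not every library correlated best with its own number. The 0.34, of WT replicate 3 with KO replicate 3, was the highest of all pairs of a WT with a KO library. With a replicate block, and without WT replicate 4, 0 genes were called, 0 of them higher, and 23 lists. The pericyte call was lost there (adjusted p = 0.0985), and the medians of skeletal muscle, cardiac muscle and p53 targets were 1.32, 2.25 and 0.22.

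Values that changed sign, for which the cause was not tested, are the following log2 fold changes, of lists as medians. With limma-voom they were 0.22 for Wnt/β-catenin targets, -0.11 for TGF-β genes, 0.0949 for oxidative phosphorylation, -0.000259 for endothelium, 0.59 for T and NK cells, 0.0462 for brown adipocytes, 0.27 for nerves, 0.55 for thymocytes, 0.00144 for mitochondrially encoded genes, -0.0207 for *Mmp19* neighbours, 0.18 for *Chga*, 0.17 for *Stmn2* and 0.34 for *Dntt*. For endothelium the median was -0.00623 with upper-quartile scaling and -8.885e-05 without a filter. With the replicate block they were -0.0359 for metalloproteinases, 0.22 for T and NK cells, -0.0506 for white adipocytes and -0.0303 for sex-linked genes. Without 1 library the range was -0.0913 to 0.0215 for Wnt/β-catenin targets, -0.29 to 0.0135 for proteoglycans, -0.19 to 0.10 for endothelium, -0.30 to 0.27 for white adipocytes, -0.28 to 0.0767 for immediate early genes, -0.0904 to 0.21 for metalloproteinases, -0.50 to 0.16 for oxidative phosphorylation and -0.48 to 1.08 for T and NK cells. It was -0.84 to 0.0473 for brown adipocytes, -0.68 to 1.13 for thymocytes, -0.0975 to 0.0862 for sex-linked genes, -2.15 to 0.73 for nerves, -0.067 to 0.16 for TGF-β genes, -0.75 to 0.0622 for fatty acid oxidation, -0.49 to 0.0675 for mitochondrially encoded genes and -0.0273 to 0.12 for *Mmp19* neighbours. It was -0.0206 to 3.09 for skeletal muscle, -0.0334 to 0.51 for mesothelium, -0.0719 to 1.598 for erythroid cells, -3.37 to 1.03 for *Chga*, -3.004 to 0.62 for *Stmn2*, -1.49 to 1.05 for *Dntt*, -0.60 to 0.00827 for *mt-Nd2* and -0.53 to 0.0538 for *mt-Co3*. Among single genes and lists the remaining results kept their direction: 3405 values also kept their side of the threshold, 206 moved past it and 76 no longer passed it.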

Other observations

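The genes of this part were taken from those outside the 41 lists after their values had been seen, and only edgeR's adjusted p over all genes is given for them. Only genes whose groups do not overlap were considered, so the separation of KO from WT in this part is a condition of the choice. *Itga11*, a collagen-binding integrin subunit of activated fibroblasts, averaged 31.5 ± 5.75 CPM in KO and 10.48 ± 1.40 CPM in WT (SD, n = 3 and 4, edgeR adjusted p = 0.0692), with every KO library above every WT library. *Emp1*, an epithelial membrane protein, averaged 385 ± 95.6 and 134.7 ± 23.7 CPM, *Capn6*, a calpain without protease activity, 29.98 ± 11.02 and 7.16 ± 1.69 CPM, and *Fst*, the activin antagonist follistatin, 34.6 ± 2.55 and 13.6 ± 3.31 CPM (edgeR adjusted p = 0.165 for each). *H19*, an imprinted noncoding RNA of fetal tissue, read 131, 12.3 and 73.4 CPM in KO replicates 1, 2 and 3 and between 3.14 and 5.28 CPM in WT (edgeR adjusted p = 0.165). *C1qtnf5*, a secreted short-chain collagen-like protein, averaged 32.3 ± 1.45 CPM in KO and 15.7 ± 2.35 CPM in WT (edgeR adjusted p = 0.165).

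*B2m*, the light chain of class I molecules, averaged 604 ± 68.3 CPM in KO and 329 ± 32.5 CPM in WT, and *H2-Aa*, a chain of class II molecules, 135 ± 52.1 and 36.2 ± 9.83 CPM (SD, n = 3 and 4, edgeR adjusted p = 0.165 for both). Lower in every KO library than in any WT library were *Galnt16*, a glycosyltransferase gene (65.4 ± 14.2 against 139 ± 19.8 CPM), *Mgat5b*, another (1.26 ± 0.508 against 5.71 ± 0.72 CPM), and *Tgfb1i1*, the focal adhesion protein Hic-5 of smooth muscle (88.9 ± 17.0 against 168 ± 19.4 CPM), each with an edgeR adjusted p of 0.165.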
